A study of Mus musculus with 4 samples.

How the data were processed

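Total RNA of the dentate gyrus from mice killed 1, 2, 4 or 6 h after contextual fear conditioning was measured on 4 oligonucleotide arrays, 1 per time point. The deposited values are linear intensity, 1 value per probe set and array, and the software and settings the authors used to make them are not given in the sources used here. In the deposited table every array had the same mean intensity after the top and bottom 2% of its probe sets, controls included, were left out (500.3 on each array), so the arrays share a common scale; this is read from the values, not from a stated step. All values were above 0, with a lowest value of 1.1.

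From these values the 66 control probe sets were left out and each array was divided by its 2% trimmed mean and multiplied by the mean of the trimmed means of all arrays, which moved no array by more than a factor of 1.0006. A floor was set at the 25th percentile of all scaled values, a signal of 57.1. Values under it were set to it before taking log2, and a fold against such a value is given as at least that size. Differences are the log2 ratio of 2, 4 or 6 h to 1 h. A probe set counted as higher or lower when it was above the floor on both arrays and at least 2-fold apart. It counted as standing above the other arrays when it was above the floor and at least 2-fold above the highest of them, with those under the floor counted at the floor. No test was possible with 1 array per group. As a yardstick for single genes, the central 95% of the log2 differences of the 500 probe sets nearest in mean signal is used; it describes these arrays and holds real differences as well as error. Probe sets were called bright at a mean signal of at least 16 floors (914), a class chosen after the data were seen.

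Probe sets were named from a table of the array's probe sets, with symbols brought up to date by gene number against RefSeq (assembly GRCm38.p6), and no coordinates are given because the sources name no build. A single gene was named for 10833 probe sets and several for 396, and none for 1193, which left 8251 genes. A gene was represented by its brightest probe set, avoiding those whose suffix (f, r or i) marks possible binding to other sequences where another existed. It counted as measured when its mean over the arrays was above the floor, which held for 6888 genes.

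For each of 27 gene lists, covering responses to activity and stress, synaptic and signalling functions, cell types of the hippocampus and its surroundings, and large protein complexes, the median log2 difference of the measured genes was set among 10000 random lists of the same size matched on mean expression in 20 bins. A list was said to stand apart when its percentile was under 2.5 or over 97.5. Cell type lists name genes that other cells also express in part: Igf2 and Igfbp2 of the choroid plexus list are also genes of the meninges and vessels. A second choroid plexus list, a second oligodendrocyte list and a leptomeninges list were added after the data were seen. The 27 lists, the scaling, the floor, the comparisons, all alternatives but the last 2 named here and the rule for named genes were fixed before the data were examined. That rule took, per comparison, the 8 largest differences in each direction among probe sets with a mean signal of at least 4 floors (228.5), 1 gene symbol and no f, r or i suffix, up to 3 largest at-least folds in each direction, the 5 highest above all other arrays at each time, and up to 4 list members per list and comparison, largest first, with Fos, Egr1, Arc, Bdnf, Homer1, Junb, Nr4a1 and Fkbp5 always where measured. The most telling of these are given. Folr1, Mobp, Mbp, Gria1, Snap25, Hspd1, Calb1 and second probe sets of a gene were chosen after their values were seen.

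The 3 comparisons share the 1 h array. The overlap expected from this alone was simulated 100 times with unchanged arrays whose normal noise had the spread of the observed differences in 20 brightness bins, which holds real differences too. Counting and list steps were tested on data simulated from the mean of all arrays, with noise pooled over the 3 comparisons. A simulated 2 h array was compared with a simulated 1 h array. Of 100 probe sets raised 4-fold, 98.0% were at least 2-fold higher, and of 100 lowered 4-fold, 100.0% were at least 2-fold lower. These 2 shares needed a signal above the floor on at least 1 array, while the counts reported here needed both. Of 12222 unchanged probe sets, 6.41% were counted at 2-fold either way, and of 5533 unchanged ones with a mean of at least 4 floors, 2.64%. Of 100 unchanged lists of 20 genes, 6 fell outside the range, and of 100 raised by 0.5 log2, 95 stood apart. The noise was drawn from the differences between these arrays, which hold real differences too, so these shares do not measure error alone.

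The alternatives tried were the deposited values without scaling, quantile normalization, intensity-dependent loess (span 0.3), the floor doubled and halved, counts without f, r and i probe sets, the mean over all probe sets of a gene, and lists over all members on the array. The 2 h array as the reference and a mean signal of at least 4 floors were added after the data were seen. Signals of the 9 probe sets for 4 spiked-in control transcripts were all lower at 2, 4 and 6 h than at 1 h (medians of -0.24, -0.52 and -0.53 log2), with the same direction under quantile and loess scaling. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.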

Results

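The series followed the dentate gyrus, the part of the hippocampus that receives most cortical input, in young male C57BL/6J mice after contextual fear conditioning, a task in which an animal learns to link a place with a foot shock. Each mouse received 3 foot shocks of 0.5 mA and 1 s, each after 2 min in a new place, and total RNA was taken 1, 2, 4 or 6 h after the last of them. Every time point was measured on 1 oligonucleotide array with 12422 probe sets for transcripts, which gives 4 arrays with no replicates, and no unshocked group was analysed here. The differences given therefore have no replicate check and carry no p-value; the number of arrays limits their precision. The median signal was 194 at 1 h, 184 at 2 h, 212 at 4 h and 197 at 6 h, and between 73.3% (2 h) and 76.9% (4 h) of probe sets lay above the floor of 57.1. Spearman's rho between arrays, taken across probe sets, which are not independent replicates, ranged from 0.905 for 1 h and 4 h to 0.926 for 2 h and 6 h.

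The comparison of 2 h with 1 h asks which transcripts differed soon after training. Choroid plexus genes, which mark the epithelium that makes cerebrospinal fluid, were lower at 2 h: 5 of the 7 measured genes were at least 2-fold lower and the list median was -1.20 on the log2 scale. Ttr, which encodes the thyroxine carrier transthyretin, had a signal of 4183 at 1 h and 565 at 2 h and was 7.41-fold lower. Igf2, a growth factor, was 2.77-fold lower, Kl, which encodes klotho, was 2.29-fold lower, and F5, coagulation factor V, was at least 2.99-fold lower. Folr1, a folate receptor of the same epithelium, went the other way, from 145 to 207. The list median lay at percentile 0.01 of 10000 random lists matched on brightness.

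Genes of neuronal activity showed no common direction at 2 h. Of the 23 measured immediate-early transcription factors, 1 was at least 2-fold higher, 1 at least 2-fold lower and 19 within 2-fold, with Zfp36 under the floor on 1 array and Fosl1 on both, and the list median was 0.06 (percentile 77.6). Junb was 2.51-fold higher, on a probe set whose design allows binding to related sequences, Nr4a1 was 1.79-fold higher and Maff was 2.23-fold lower. Junb lay just above the central 95% of 500 probe sets of similar brightness, and Nr4a1 and Maff lay inside it. Fos had a signal of 311 at 1 h and 325 at 2 h, and Egr1 had 1404 and 1088. Among 22 measured effector genes of activity the median was 0.16 (percentile 93.6). Plk2, a kinase that acts at synapses, was 1.95-fold higher at 4918 and lay above the central 95% of 500 probe sets of similar brightness. Bdnf, a neurotrophin, had 4532 at 1 h and 3621 at 2 h, Homer1 had 59.4 and 103.6, and Gadd45g was 2.01-fold lower. Bdnf, Homer1 and Gadd45g lay inside the central 95% for their brightness. No probe set was named for Arc.

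Several abundant synaptic transcripts were lower at 2 h. Nsf, the ATPase that recycles membrane fusion complexes, was 2.35-fold lower (13782 at 1 h, 5852 at 2 h), Cplx2, which encodes complexin 2, was 2.28-fold lower, Nrgn, which encodes the calmodulin-binding protein neurogranin, was 1.94-fold lower and Stx1a was 1.69-fold lower. All 4 lay below the central 95% of probe sets of similar brightness. The synaptic list as a whole had a median of -0.15 over 18 genes (percentile 2.43), with 10 of them lower and 8 higher. Glutamate receptor genes had a median of -0.62 over 10 genes (percentile 0.26), 7 of them lower and 3 higher. Gria3 was 2.83-fold lower, Grm8 2.58-fold lower and Grin2b at least 2.95-fold lower, while Grin2a was at least 2.19-fold higher. The 3' over 5' signal ratio of the control transcripts, a sign of RNA or copy length, was also higher at 2 h: 3.84 against 2.51 for beta-actin and 5.44 against 3.88 for Gapdh.

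Markers of other cells differed between the same arrays. Oligodendrocyte genes had a median of 0.38 at 2 h (percentile 99.6; 10 of 11 measured genes higher), led by Gsn at 2.16-fold and the myelin gene Mog at 1.75-fold. Interneuron genes had a median of 0.30 over 14 genes (percentile 99.3), 8 of them higher and 5 lower, with Dlx1 2.34-fold higher and Pvalb at -0.81 log2. The 4 measured CA1 pyramidal cell genes had a median of 0.51 (percentile 98.4), with Ccn3 2.39-fold higher. Microglia and macrophage genes had a median of -0.31 over 12 genes (percentile 1.44), 9 of them lower and 3 higher, with Cd68 2.22-fold and C1qc 1.71-fold lower, while Cx3cr1 was 2.98-fold higher.

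Single genes outside these groups also differed at 2 h, among probe sets with a mean signal of at least 4 floors and above the floor on both arrays. Krt81, a hair keratin gene, had a signal of 147 at 1 h and 1112 at 2 h and was 7.59-fold higher, followed by Ddr2 (5.63-fold), Cars (5.18-fold), Chst3 (4.87-fold) and Gm8096 (4.72-fold). Trim13, Ighd and Tcf25 were 4.61-fold, 4.49-fold and 4.17-fold higher. After Ttr, the lowest were Mmp16, a membrane metalloprotease gene (6.78-fold lower), Prss30 (6.51-fold), Tacr2 (5.65-fold), Snx17 (5.56-fold) and the histone acetyltransferase gene Kat2a (4.96-fold). Against signals under the floor, Olfr94 was at least 5.89-fold higher, and Anpep, Prss32 and Mphosph10 were at least 6.10-fold, 5.99-fold and 5.96-fold lower. Manf and Dnajc3, both genes of the endoplasmic reticulum stress response, were 2.22-fold and 2.18-fold higher, although their list had a median of 0.13 (percentile 88.5). In all, 273 probe sets (2.2%) were at least 2-fold higher and 361 (2.91%) at least 2-fold lower than at 1 h. Of unchanged simulated probe sets, 6.41% were counted at 2-fold either way, with noise that holds real differences too. Among the 5733 probe sets with a mean signal of at least 4 floors, 111 were at least 2-fold higher and 132 lower. There the simulated unchanged share was 2.64% either way. As the noise was drawn from these same arrays, the counts alone cannot tell change from noise. Only 8 of the higher and 9 of the lower ones were among the 2031 probe sets with a mean signal of 914 or more. The excess of lower probe sets at 2 h was absent under loess scaling (326 higher, 321 lower) and quantile normalization (339 and 315). The calls for synaptic, glutamate receptor, interneuron and microglia lists ended under at least 1 alternative: with the mean over all probe sets of a gene the synaptic and glutamate receptor medians were -0.04 and -0.23, with the floor doubled the interneuron median was 0.11, and over all members on the array the microglia median was -0.12.

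**Figure D1:**
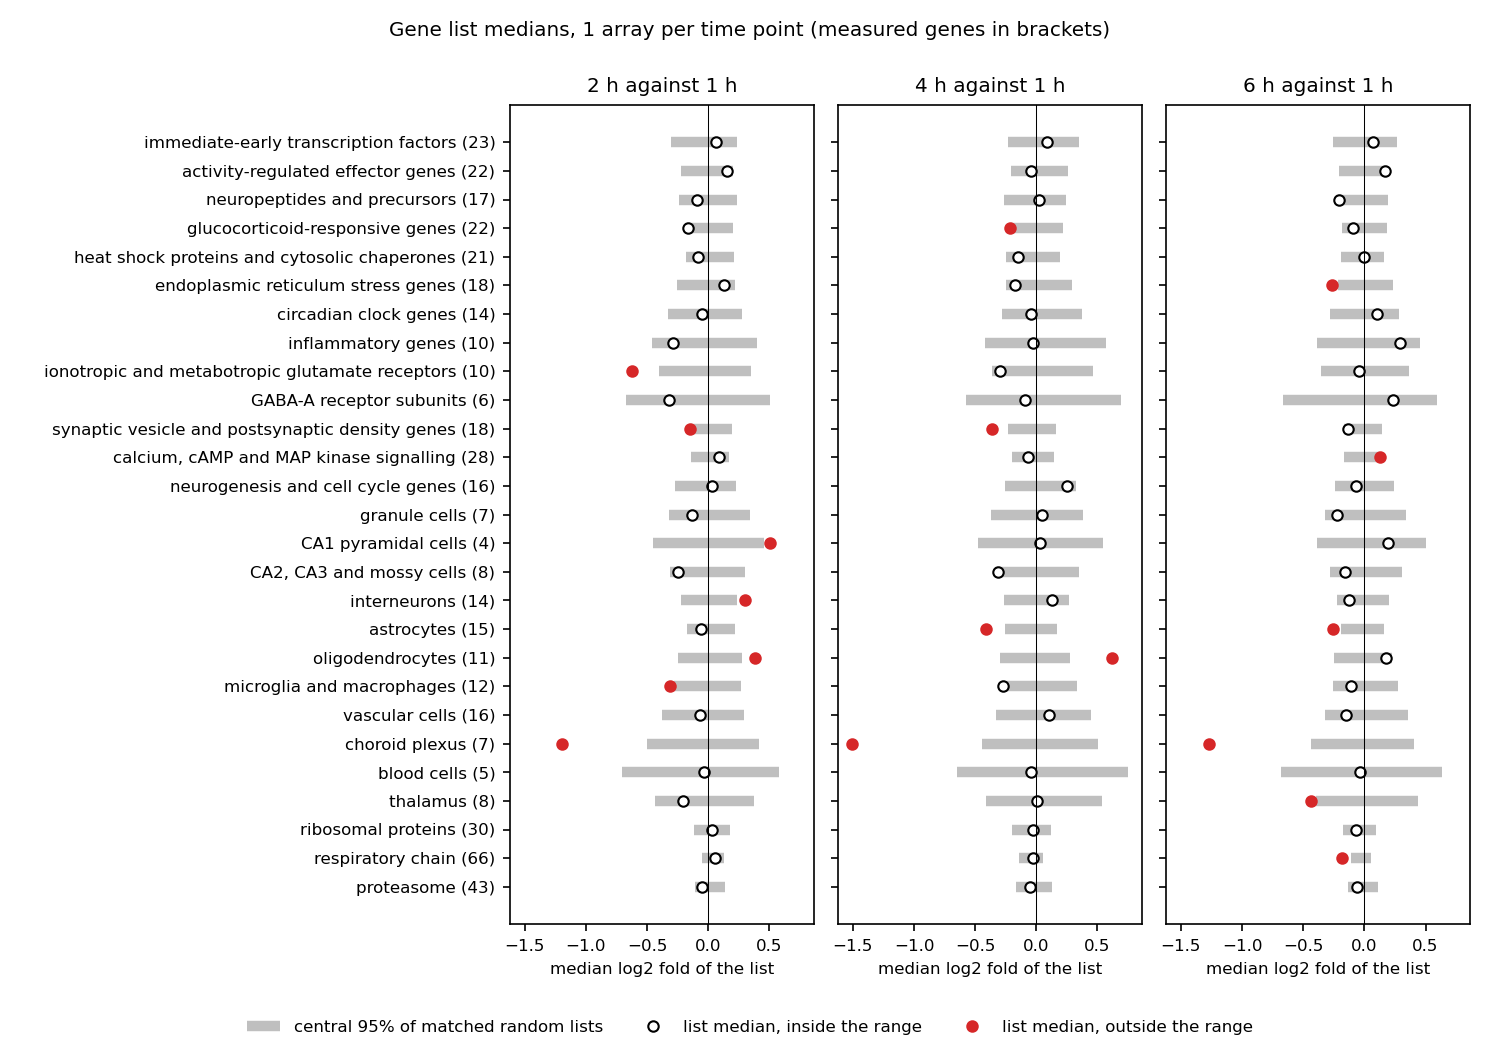
Median log2 fold of each fixed gene list at 2, 4 and 6 h against 1 h (x axis, log2 units; 1 array per time point), with grey bars for the central 95% of 10000 random lists matched on brightness and red points for medians outside them. The choroid plexus list lies far to the left in all 3 panels (-1.20, -1.51 and -1.27), and the oligodendrocyte list lies farthest to the right at 4 h (0.62).

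The comparison of 4 h with 1 h asks which transcripts differed later in the same course. Choroid plexus genes were again lower, with Ttr at 372 and 11.25-fold lower, Kl 4.31-fold, Igf2 2.84-fold and F5 at least 2.99-fold lower. Their list median was -1.51 (percentile 0.00), with 4 of 7 genes at least 2-fold lower and Folr1 2.22-fold higher. A second list of 20 measured choroid plexus genes, added after the data were seen, had a median of -0.19 at 4 h (percentile 6.72), inside the random range. Oligodendrocyte genes were higher, with a median of 0.62 (percentile 99.96) and all 11 measured genes above their 1 h signal. Mog was 2.59-fold, Gsn 1.96-fold and Mal 1.80-fold higher, and Mobp, the brightest of the list, was 1.39-fold higher, while Mbp had 3681 at 1 h and 3719 at 4 h. A second oligodendrocyte list, added after the data were seen, had a median of 0.13 over 16 genes (percentile 77.8), inside the random range. Genes of the leptomeninges, the membranes around the brain, in a list added after the data were seen, were also higher at 4 h, with a median of 0.43 over 18 genes (percentile 99.4). None of the added lists was recomputed under the alternative settings. Astrocyte genes were lower, with a median of -0.41 (percentile 0.03) and 12 of 15 genes below their 1 h signal. Among them the water channel gene Aqp4 was 2.32-fold and Fgfr3 2.08-fold lower, S100b was 1.70-fold lower, and the glutamate transporter gene Slc1a2 was at 0.77 log2 in the other direction.

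Synaptic genes were lower at 4 h in 16 of 18 cases, with a median of -0.36 (percentile 0.04). Nsf was 2.56-fold, Cplx2 2.22-fold and Gap43, a growth cone gene, 2.01-fold lower, and Homer2 was 2.16-fold higher. Gria1, the AMPA receptor subunit gene, had 6021 at 1 h and 3239 at 4 h on its brighter probe set and 675 and 557 on its other. Gabra2, a GABA-A receptor subunit gene, was 11.32-fold lower (700.3 against 61.9), although the 6 measured genes of that family had a median of -0.09 (percentile 32.1). On the same array the leptomeninges list stood at 0.43, and the 3' over 5' ratio was 3.21 for beta-actin and 6.88 for Gapdh, against 2.51 and 3.88 at 1 h. Both ratios stayed higher at 2 h and at 4 h than at 1 h under quantile and loess scaling as well.

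Glucocorticoid-responsive genes had a median of -0.16 at 2 h (percentile 4.82), inside the random range. With the mean over all probe sets of a gene the 2 h median was -0.37 (percentile 0.03), outside it. At 4 h the median was -0.22 over 22 genes (percentile 2.28), 13 of them lower. Over all members on the array the 4 h median was -0.18 (percentile 3.05), inside the range. Tsc22d3, which encodes the steroid-induced leucine zipper protein GILZ, was at least 4.56-fold lower, the cell cycle inhibitor gene Cdkn1a was 4.18-fold lower, Bcl6 was 2.26-fold lower and Map3k6 at least 2.60-fold lower. Fkbp5, a co-chaperone of the glucocorticoid receptor, had 1303 at 1 h and 827 at 4 h. Immediate-early transcription factors had a median of 0.09 (percentile 63.6), with none of 23 at least 2-fold higher. Egr2 was at least 4.23-fold and Fosl2 2.46-fold lower, while Btg2 was 1.94-fold and Junb 1.74-fold higher. Egr2 and Btg2 lay outside the central 95% of probe sets of similar brightness, and Fosl2 and Junb inside it. Fos had 220.5, Egr1 1176 and Nr4a1 299. Activity effector genes had a median of -0.04 (percentile 28.2), with the protease inhibitor gene Timp1 1.85-fold higher, Bdnf at 3938, and Homer1 below the floor.

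Among probe sets with a mean signal of at least 4 floors and above the floor on both arrays, the noncoding RNA gene Meg3 showed the largest difference upward at 4 h, 9.74-fold (221 against 2155); its other probe set, at 511 and 1129, was at 1.15 log2 in the same direction. Rce1 (7.53-fold), Ighd (7.02-fold), Rgs11 (6.80-fold), Gm8096 (6.69-fold), Tcf25 (6.68-fold), Cars (6.62-fold) and Krt81 (5.74-fold) followed. Against signals under the floor, Vax2 was at least 7.76-fold higher and Lipa at least 5.74-fold lower. Downward, Gabra2 and Ttr were followed by Ap5s1 (7.06-fold), Zbtb2 (6.97-fold), Errfi1 (5.91-fold), Kat2a (5.60-fold), Ptp4a3 (5.31-fold) and the centromere protein gene Cenpb (4.82-fold). Errfi1 had a brighter probe set that stayed at 0.03 log2. Hspd1, a mitochondrial chaperone gene, was 2.32-fold lower within a heat shock list whose median was -0.15 (percentile 11.9).

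At 4 h, 503 probe sets (4.05%) were at least 2-fold higher and 365 (2.94%) at least 2-fold lower than at 1 h. The simulated unchanged share was 6.41% either way. With a mean signal of at least 4 floors, 191 were higher and 145 lower of 5733, beside a simulated share of 2.64%. Of the observed ones, 8 and 17 were bright. The excess of higher ones was absent under loess scaling (382 higher, 409 lower) and quantile normalization (420 and 433) and larger with the 2 h array as reference (488 and 257). With that reference the 4 h medians of the choroid plexus (-0.04), oligodendrocyte (0.02), synaptic (-0.07) and glucocorticoid (-0.02) lists lay inside the random range, while that of the astrocyte list (-0.27, percentile 1.46) did not.

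**Figure D2:**
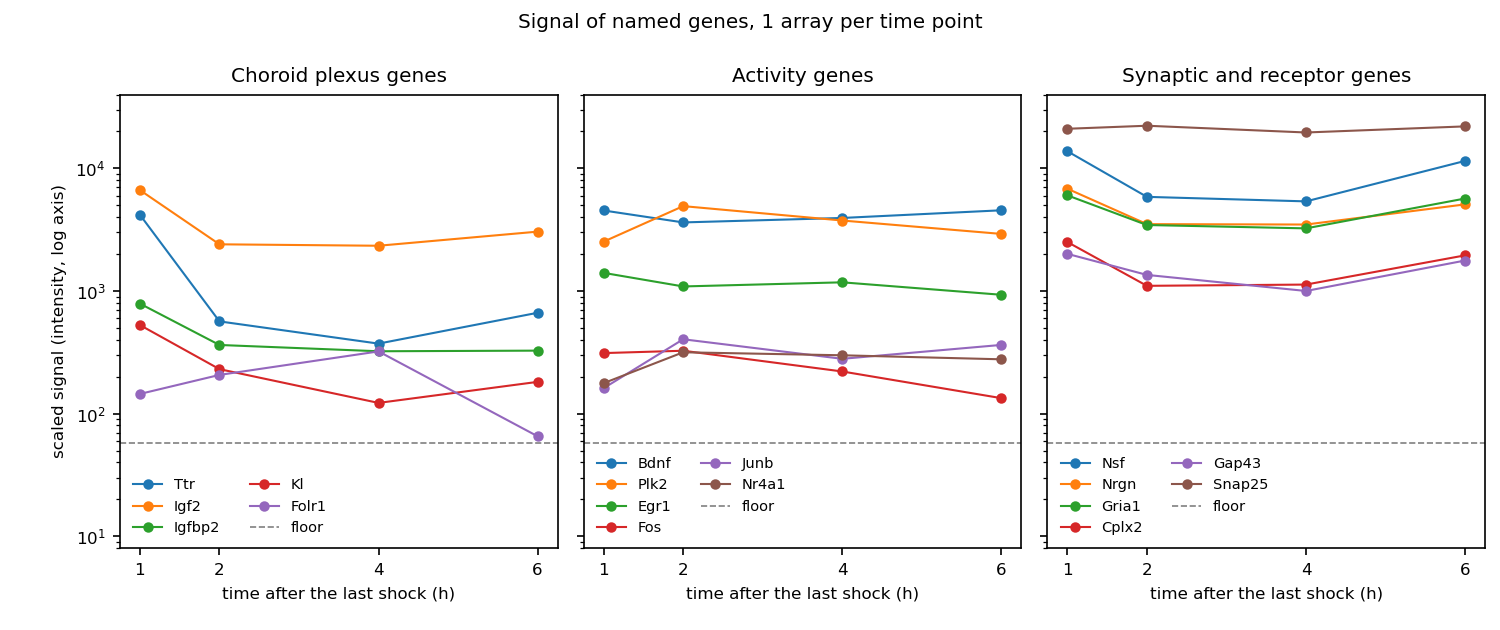
Scaled signal (intensity, log axis) of named genes against hours after the last shock, 1 array per point, with the floor of 57.1 as a dashed line. Ttr is at 4183 at 1 h and at 372 to 664 later, Fos stays between 134 and 325, and Nsf is at 5852 and 5377 at 2 h and 4 h but at 13782 and 11496 at 1 h and 6 h.

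The comparison of 6 h with 1 h asks what differed at the end of the course. Genes of the respiratory chain, the mitochondrial complexes that make ATP, were slightly lower: 47 of 66 measured genes lay below their 1 h signal and the median was -0.18 (percentile 0.01), with none at least 2-fold lower on signals above the floor. Ndufa1 was at least 3.31-fold lower and Ndufa9 was at -0.64 log2, while Cox8a was at 0.97. Endoplasmic reticulum stress genes had a median of -0.27 over 18 genes (percentile 0.88), 12 of them lower, with Pdia3 4.63-fold lower, Ppp1r15a 1.92-fold, the chaperone gene Hspa5 1.67-fold and Xbp1 1.63-fold lower. Astrocyte genes had a median of -0.26 (percentile 0.33; 11 of 15 lower), with Aqp4 1.80-fold and the metallothionein gene Mt3 1.64-fold lower.

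Choroid plexus genes were lower at 6 h too, with a median of -1.27 (percentile 0.00) and all 7 genes below their 1 h signal. Ttr was 6.30-fold lower, Calml4 at least 4.10-fold, Kl 2.91-fold and Igfbp2 2.42-fold lower, and Folr1 had 65.3. Thalamus markers had a median of -0.43 over 8 genes (percentile 1.59), 6 of them lower and 2 higher, with Lef1 2.38-fold and Ramp3 2.07-fold lower and Zic1 2.09-fold higher. Calcium, cAMP and MAP kinase genes had a median of 0.13 over 28 genes (percentile 98.2), 17 of them higher and 10 lower, with Camk4 at least 3.06-fold lower and Calm2 at -0.86 log2 against the list. Synaptic genes had a median of -0.13 (percentile 7.11) and oligodendrocyte genes one of 0.17 (percentile 94.3), both inside the random range. Nsf was at 11496 and Gria1 at 5675, and the 3' over 5' ratios were 2.60 for beta-actin and 4.51 for Gapdh.

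Activity genes again went both ways at 6 h. Fos was 2.33-fold lower at 134, Egr1 had 931, Egr2 was 2.62-fold lower and Fosl2 at least 2.61-fold lower. Junb was 2.25-fold higher and Nr4a1 had 277. All of these lay inside the central 95% of probe sets of similar brightness. The immediate-early list had a median of 0.07 (percentile 73.8) and the effector list one of 0.17 (percentile 96.6). Among the effectors Tiparp was 2.05-fold lower, Bdnf was at 4548 and Homer1 at 73.1, all inside that central 95% as well. Glucocorticoid-responsive genes had a median of -0.09 (percentile 16.1), with Cdkn1a 2.73-fold lower and Fkbp5 at 1242; with the mean over all probe sets of a gene their median was -0.30 (percentile 0.13), outside the random range. Among probe sets with a mean signal of at least 4 floors and above the floor on both arrays, Meg3 was at 2150.1, 9.71-fold above 1 h (511 and 704 on its other probe set), and Krt81 was 7.19-fold, Chst3 5.39-fold and the bradykinin receptor gene Bdkrb1 5.35-fold higher. Dusp2, an immediate-early phosphatase gene, was 8.24-fold lower (658.5 against 80.0), followed by Hira (6.32-fold), Ttr (6.30-fold), Col7a1 (6.12-fold), Rsl1d1 (6.00-fold) and H2-Q10 (5.76-fold). Against signals under the floor, Olfr94 was at least 10.35-fold and Vax2 at least 7.51-fold higher, and Hrh2 was at least 6.13-fold lower.

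At 6 h, 341 probe sets (2.75%) were at least 2-fold higher and 344 (2.77%) at least 2-fold lower than at 1 h. The simulated unchanged share was 6.41% either way. With a mean signal of at least 4 floors, 148 were higher and 103 lower of 5733, beside a simulated share of 2.64%. Of the observed ones, 12 and 10 were bright. Against the 2 h array the counts were 343 and 246. With the 2 h array as reference the choroid plexus (-0.15), thalamus (-0.28) and calcium, cAMP and MAP kinase (0.03) lists lay inside the random range and the respiratory chain, endoplasmic reticulum stress and astrocyte lists did not; taking the mean over all probe sets of a gene turned the thalamus median to 0.01 and ended the respiratory chain (-0.11) and astrocyte (-0.13) calls, and halving the floor ended that of endoplasmic reticulum stress genes (-0.21). With the 2 h reference the 6 h medians of synaptic (0.18), immediate-early (-0.15), glucocorticoid-responsive (0.12) and oligodendrocyte (-0.07) genes had the opposite sign, and the synaptic one lay outside the random range.

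With the processing described, the remaining groups lay inside the random range at every time. Granule cell genes, which mark the principal neurons of the dentate gyrus, had medians of -0.13, 0.05 and -0.23 at 2, 4 and 6 h over 7 genes, with Calb1 at 3035, 2405, 2296 and 2158 from 1 h to 6 h. Genes of CA2, CA3 and mossy cells had -0.24, -0.32 and -0.16 over 8 genes. Neuropeptide genes had -0.10, 0.02 and -0.21. Among them Tac2, which encodes neurokinin B, was 3.41-fold higher at 2 h, 4.77-fold higher at 4 h and under the floor at 6 h. Its difference lay inside the central 95% of probe sets of similar brightness at 2 h and above it at 4 h. Clock genes had -0.05, -0.05 and 0.10, inflammatory genes -0.29, -0.03 and 0.29, and genes of neurogenesis and the cell cycle 0.03, 0.25 and -0.07. Vascular genes had -0.06, 0.10 and -0.15 and blood genes -0.04, -0.05 and -0.04. Ribosomal protein genes had 0.03, -0.02 and -0.07 and proteasome genes -0.05, -0.05 and -0.06. GABA-A receptor subunits had -0.32 at 2 h and 0.24 at 6 h, and heat shock genes -0.08 at 2 h. Over all 27 lists and 3 comparisons, 18 of 81 medians lay outside the range. About 4.0 would by chance if the genes of a list varied independently, as those of the random lists were drawn. Genes of 1 list that move together on an array raise that number, so the excess does not measure a departure from chance. The shared 1 h array also makes the 3 comparisons dependent.

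A last set of comparisons asks which transcripts stood above all 3 other arrays at 1 time point. At 1 h, Ttr (6.30-fold above the next array), Btbd3 (2.38-fold), the neurotrophin receptor gene Ntrk3 (2.34-fold), Kl (2.29-fold) and Igf2 (2.18-fold) stood highest among probe sets with a mean signal of at least 4 floors, and 171 probe sets of any brightness were at least 2-fold above the others. At 2 h the leading genes were Gna11 (2.38-fold), Manf (1.98-fold), Zranb1 (1.94-fold), Dnajc3 (1.85-fold) and Hk1, a hexokinase gene (1.79-fold), and 80 probe sets of any brightness passed 2-fold. At 4 h they were the kinase gene Tyk2 (3.02-fold), Pycrl (2.81-fold), Entpd2 (2.22-fold), Cyp2b10 (2.19-fold) and Stx2 (2.12-fold), with 269 past 2-fold at any brightness. At 6 h they were Sh3bp1 (3.20-fold), Pcsk6 (2.45-fold), Spr (1.98-fold), Mdn1 (1.97-fold) and Nexmif (1.86-fold), with 125. Most of these probe sets were dim: with a mean signal of at least 4 floors, a limit chosen after the data were seen, the counts were 9, 2, 12 and 4.

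Krt81, Gm8096 and Tcf25 were among the largest upward differences at 2, 4 and 6 h alike, and Ttr was among the largest downward ones. In all, 74 probe sets were at least 2-fold higher and 23 at least 2-fold lower than at 1 h in all 3 comparisons. Simulated unchanged arrays set against the same 1 h array gave 33.8 and 59.1 on average. The sizes of the simulated sets were not counted, and sets of unlike size share unlike numbers. The simulation therefore cannot show whether the observed overlap was above or below that from a shared reference. Pairs of comparisons shared 120 (2 and 4 h), 124 (2 and 6 h) and 152 (4 and 6 h) higher probe sets, where the simulation gave 92.5, 91.9 and 93.4 and independent sets would share 17.4, 11.8 and 21.4. For lower probe sets the pairs shared 93, 74 and 72, with 128.0, 125.8 and 128.4 simulated and 16.7, 15.7 and 15.7 for independent sets. For 297 genes, 2 probe sets had a mean signal of at least 4 floors and no f, r or i suffix. The brighter was at least 2-fold different for 5, 5 and 2 genes at 2, 4 and 6 h. The second was so as well in the same direction for 0, 2 and 0. Across these genes Spearman's rho between the log2 differences of the 2 probe sets was only 0.08, 0.23 and 0.19. The folds of single probe sets were thus poorly matched by a second probe set of the same gene.

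**Figure D3:**
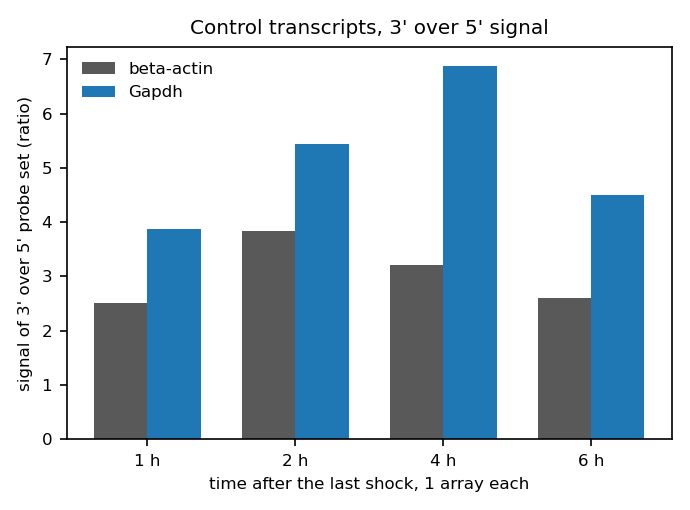
Ratio of the signal of the 3' probe set to that of the 5' probe set (y axis, from 0) for beta-actin and Gapdh on each of the 4 arrays, 1 bar per array. Both ratios are higher at 2 h (3.84 and 5.44) and 4 h (3.21 and 6.88) than at 1 h (2.51 and 3.88) and 6 h (2.60 and 4.51).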

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

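The 2 h array as reference and the limit of at least 4 floors on the mean signal were chosen after the data were seen. Medians were recomputed singly for lists that stood apart and for the immediate-early, effector, glucocorticoid, synaptic and oligodendrocyte lists at every time; for the others only the number of lists outside the random range was recounted, and 13 (mean over probe sets) to 19 (quantile and loess) of 81 lay outside it, against 18 as reported. Across all settings 179 of these medians kept their call without a change of sign, 26 lost a call, 4 gained one and 5 changed sign. Of the counts, 48 stayed within 1.5 times the reported count and 33 did not. With the values as deposited none of these calls or counts moved this far, and without f, r and i probe sets, run for counts alone, no count did. With the floor doubled, 98, 212 and 145 probe sets were at least 2-fold higher and 144, 151 and 107 lower at 2, 4 and 6 h, and 32, 17, 81 and 38 stood above the other arrays at 1, 2, 4 and 6 h. With the floor halved these were 561, 902 and 697 higher, 739, 699 and 653 lower, and 298, 185, 417 and 218. With a mean signal of at least 4 floors they were 111, 191 and 148 higher, 132, 145 and 103 lower, and 9, 2, 12 and 4; fewer probe sets enter under a higher limit. Under loess 138 and 163 stood above the others at 2 h and 4 h, and under quantile normalization 121 at 2 h. Log2 medians lost their call as follows. With the floor doubled they were 0.11 for interneurons, -0.24 for glutamate receptors, -0.27 for microglia and -0.15 for synaptic genes at 2 h. With the floor halved they were -0.12 for synaptic genes at 2 h and -0.21 for endoplasmic reticulum stress genes at 6 h. Over all members on the array they were 0.14 for interneurons, -0.24 for glutamate receptors, -0.12 for microglia and -0.083 for synaptic genes at 2 h, -0.18 for glucocorticoid-responsive genes at 4 h and 0.10 for calcium, cAMP and MAP kinase genes at 6 h. With the mean over probe sets they were -0.23 for glutamate receptors, -0.23 for microglia and -0.04 for synaptic genes at 2 h, and -0.13 for astrocytes, 0.08 for calcium, cAMP and MAP kinase genes and -0.11 for the respiratory chain at 6 h, while the thalamus median at 6 h reversed to 0.013. Quantile normalization gave -0.17 for astrocytes at 6 h. With the 2 h array as reference the 4 h medians were -0.039 for choroid plexus, -0.024 for glucocorticoid-responsive genes, 0.021 for oligodendrocytes and -0.067 for synaptic genes, and the 6 h medians -0.15 for choroid plexus, -0.28 for the thalamus and 0.033 for calcium, cAMP and MAP kinase genes. With that reference the 6 h medians changed sign for synaptic genes (0.18, now outside the random range) and, inside the range before and after, for immediate-early (-0.153), glucocorticoid-responsive (0.12) and oligodendrocyte genes (-0.074). Calls were gained for activity effectors at 6 h under loess (0.19), and for glucocorticoid-responsive genes at 2 h under quantile normalization (-0.18) and at 2 h and 6 h with the mean over probe sets (-0.37 and -0.30). Except where fewer or more probe sets enter, the cause was not tested. Signal over background is a limit beside the number of arrays: the SD of log2 differences between 4 h and 1 h, which holds real differences too, was 0.94 for dim probe sets and 0.37 for bright ones.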

Other observations

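The tests with a second choroid plexus list and a second oligodendrocyte list were set before their results were seen, and all others in this part were chosen after, with some of their bounds set once values were known. Several abundant transcripts outside the fixed lists differed between arrays. Ptgds, which encodes prostaglandin D synthase of the meninges and choroid plexus, had signals of 8455, 14505, 19289.9 and 24314 at 1, 2, 4 and 6 h, on a probe set that can bind related sequences. Eif4a2, a translation initiation factor gene, had 4621 at 1 h and 10359, 7741 and 7943 later. Fabp7, a fatty acid binding protein gene of radial glia and astrocytes, had 1831 and 2408 at 1 h and 2 h and 591 and 892 at 4 h and 6 h. Igf1r, the receptor gene for insulin-like growth factor 1, had 2255 at 1 h and 792 at 4 h, Laptm4a had 3342 at 1 h and 1228 at 6 h, and Arl2bp had 5503 at 1 h and 2518 at 6 h. A probe set without a gene name had 11091 at 1 h and 2552, 1769 and 3999 later, a course like that of Ttr.

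Choroid plexus genes were high on the 1 h array, with a median log2 of 1.33 for 7 genes against the mean of the other 3 arrays. As a set, 18 measured genes of the leptomeninges, without Igf2 and Igfbp2, were not higher at 1 h (median -0.034, percentile 46.0, bootstrap -0.50 to 0.13). At 4 h against 1 h that list stood apart upward, at 0.43 (percentile 99.4). Its 4 h rise lowers its 1 h value against the mean of the other 3 arrays. The bound used to judge its interval was set after the result, and the interval of the second choroid plexus list lies under it too. Leptomeningeal tissue as a source was therefore not settled. Choroid plexus tissue in the 1 h sample may account for the pattern: 20 measured genes of a second choroid plexus list had a median of 0.408, at percentile 99.6 of random lists, with 12 of them higher at 1 h, though at 4 h against 1 h alone its median of -0.19 (percentile 6.72) lay inside the random range. Its bootstrap interval of -0.21 to 0.57 includes 0, Ptgds, a gene of both tissues, was lowest at 1 h, its most abundant genes were Slc12a2 (967, 817, 502 and 686 at 1, 2, 4 and 6 h) and Car12 (528, 332, 406 and 413), and how many of its genes the dentate gyrus itself expresses was not analysed here. A change with time after the shocks cannot be told apart from it, because each time point has 1.0 array.

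Synaptic genes were lower on the 4 h array than on the 1 h array, with a median of -0.36 over 18 genes. On that 4 h array the leptomeninges list stood at 0.43 against 1 h. Against the 2 h array the 4 h synaptic median was -0.07 (percentile 44.2), inside the random range. Lower signal of long genes is argued against as the whole cause: the longest genes (spans over 47.2 kb, 9 of the 18 among them) had a median -0.069 from that of the shortest (at most 8.4 kb) at 4 h (bootstrap -0.11 to -0.03). RNA or labelled copy shortened at its 5' end may contribute. The 3' over 5' ratio of both control transcripts was higher at 4 h than at 1 h, by a factor of 1.277 for beta-actin and 1.77 for Gapdh. It was also higher at 2 h (1.53 and 1.40), where the synaptic median was -0.15, and at 6 h (1.03 and 1.16), where the median was -0.13. The ratio was thus raised mainly on the 2 h and 4 h arrays. Beta-actin was highest at 2 h and Gapdh at 4 h, so the ratio does not set the 4 h array apart from the 2 h array. Where each synaptic probe set lies in its transcript was not analysed here. A change of the whole transcript stays open, because a single other probe set of these genes was bright enough, one of Napb at -1.309 log2. A biological change with time stays open as well and was not tested, since each time point has 1 array.

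Oligodendrocyte genes were higher on the 4 h array than on the 1 h array. Their median was 0.62 over 11 genes, beside the leptomeninges median of 0.43 against 1 h. At 2 h against 1 h their median was 0.38, and at 4 h against 2 h it was 0.02 (percentile 69.4). At 6 h against 1 h the median was 0.17 (percentile 94.3), inside the random range. The pattern was therefore shared by the 2 h and 4 h arrays and not particular to 4 h. More oligodendrocytes in the 4 h sample than in the 1 h sample may account for it but cannot be told apart from other sources. The 16 measured genes of a second list had a median of 0.131, at percentile 77.8, inside the random range. The most abundant of them, Fth1, had 14867 at 1 h and 10647 at 4 h. An equal rise of all oligodendrocyte transcripts is also undecided: the higher of 2 Mbp probe sets was at 0.015, but probe sets of its brightness scatter by 0.66 either way. A change with time after the shocks was not tested, since each time point has 1 array.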
